A study of Mus musculus with 19 samples.

How the data were processed

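Total RNA of gastrocnemius muscle was sequenced in 19 libraries made with a TruSeq RNA kit. The authors deposited 1 table of expression values in TPM, transcript abundances corrected for transcript length, for 55401 genes and 19 libraries, rounded to 2 decimals, in which each library sums to 1e+06 within 1.02. Their processing notes name STAR 2.7.1a, RSEM 1.3.1 and the GRCm38 genome, and the annotation release is not given in the sources used here. TPM keep no read counts, so the depth of each library is unknown and no counting interval or detection floor is given. Of the gene identifiers, 99.53% were found in release 21 of the GENCODE mouse annotation (GRCm38), which supplied the positions and gene types. Among the tested genes 48 had a symbol shared by more than 1 identifier, and identifiers were kept apart. The strand of the libraries was not used, and genes that share sequence with pseudogenes, paralogs or antisense transcripts are named as uncertain in the text.

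Groups were taken from the labels: 3 WT saline, 3 labelled Gc-KO saline, 7 WT LLC and 6 labelled Gc-KO LLC libraries. The names of 6 value columns give the Gc-KO genotype and no treatment, and these were matched by elimination to the labelled Gc-KO LLC libraries 1 to 6, the only ones without a column. No library was regrouped or left out of the main analysis.

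The 12045 genes with TPM of at least 1 in at least 3 libraries were tested in R 4.3.3 with limma 3.58.1 on log2(TPM + 1). A single fit with 4 group means and a mean-variance trend gave 5 contrasts: LLC against saline in each genotype, labelled Gc-KO against WT in saline and after LLC, and the interaction, that is, the LLC effect in labelled Gc-KO minus that in WT. Limma's moderated tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Changes are on the log2(TPM + 1) scale with their SE. Of 41 fixed gene lists, 37 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast; camera with an estimated correlation and fry were run beside it. Members are counted as called over all genes and as adjusted over the list alone. Some lists share members. The Gc transcript, whose level is near 0, was compared with exact two-sided permutation tests, and called genes within 10 Mb of Gc with Fisher's exact test. The LLC effects of the genotypes were compared by a slope through the origin. The reversal of the LLC effect was measured with odd and even WT LLC libraries in separate effects and set beside 100 simulations. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

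The contrasts, the tests, the lists, the named genes and most alternatives were chosen before the data were examined. Named genes were Gc, Fbxo32, Trim63, Fbxo30, Map1lc3b and Foxo1 in every comparison; the 8 largest rises and 8 largest falls among called genes with a mean TPM of at least 5 in a compared group, without gene models that lack a proper name; and up to 4 members with the smallest adjusted p of each list with at least 3 called members or a camera adjusted p under 0.05. Where fewer than 6 genes passed, all were named, with the 3 smallest p in each direction as not passing. Some of these are summarised. Cox18, Gm14165, Rplp0, Rplp0-ps1, Ctdnep1, Kmt5a, Pon3, Gm24830, Gm26232, 7530428D23Rik, the genes of structural RNAs and those of liver were named after their values were seen.

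Alternatives were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, median ratio scaling, quantile normalization, mitochondrial-encoded genes left out, only the groups compared, no trend, array weights, replicate numbers as a block, and each library left out in turn. Added after the data were seen were WT LLC 4 and labelled Gc-KO LLC 3 left out, alone and with scaling, labelled Gc-KO LLC 5 and 6 left out, labelled Gc-KO LLC 1 to 4 left out, the structural RNA share as a covariate, nuclear protein-coding genes alone rescaled to the same sum, a permutation test of list means per library, alone and without WT LLC 4 and labelled Gc-KO LLC 3, and, for the lists, the share as a covariate and each library left out in turn. The pipeline was tested on simulated data with 200 of 12045 genes changed. At a log2 change of 1 it recovered 78% for LLC in WT, 78% for LLC in labelled Gc-KO, 59.5% for the genotypes in saline, 91.5% for the genotypes after LLC and 35% for the interaction. At a log2 change of 2 it recovered 98%, 95.5%, 97%, 99% and 87%. False calls made up 2.66% to 7.89% of calls. The simulated errors were independent between genes, without the shifts that real libraries share, so recovery in the real data can be lower.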

Results

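Gastrocnemius muscle, a fast-fibre muscle of the lower hind limb, was profiled by RNA sequencing in 19 libraries from mice of the C57BL/6 strain that were 3 months old. Some mice were wild type (WT) and others were labelled Gc-KO, that is, knockouts of Gc, the gene of vitamin D binding protein. This plasma protein, made mainly by the liver, carries vitamin D metabolites and binds actin released from cells. Muscle was taken on day 23 after an injection of saline or of Lewis lung carcinoma (LLC) cells, a transplantable mouse lung tumour line used as a model of cancer-associated wasting. The 4 groups held 3 WT saline, 3 labelled Gc-KO saline, 7 WT LLC and 6 labelled Gc-KO LLC libraries. The design asks how muscle RNA differed after LLC injection, whether it differed with the Gc genotype, and whether the response to LLC cells differed with the genotype. Values were TPM, transcript abundances corrected for transcript length that have the same sum in every library and keep no trace of sequencing depth, so the depth of each library is unknown. The labels do not state in so many words that each library came from another mouse, so p-values measure the spread between these libraries.

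The Gc transcript was higher, not lower, in the libraries labelled Gc-KO. In saline muscle Gc (chromosome 5, 89417522 to 89457898, GRCm38) stood at 2.35 ± 3.64 TPM in the libraries labelled Gc-KO (SD, n = 3) and at 0.00667 ± 0.0115 TPM in WT (SD, n = 3; exact two-sided permutation p = 0.1, the smallest these group sizes allow). After LLC injection it stood at 0.383 ± 0.213 TPM in the libraries labelled Gc-KO (SD, n = 6) and at 0.0671 ± 0.178 TPM in WT (SD, n = 7; exact two-sided permutation p = 0.021). Leaving out any 1 of these 13 libraries put the exact p at 0.0541 to 0.0631, except WT LLC 4 (exact p = 0.0152 without it) and labelled Gc-KO LLC 3 (exact p = 0.0126 without it). The high saline mean came from the library labelled Gc-KO saline 2, at 6.55 TPM, against 0.22 and 0.28 TPM in the other libraries of that group. That library also held the highest level of 14 of 14 liver plasma protein genes, Gc among them, as given below. Among the LLC libraries, the library labelled WT LLC 4 held 0.47 TPM where every other WT LLC library was listed at 0, and the library labelled Gc-KO LLC 3 was listed at 0 where the others of its group held 0.28 to 0.59 TPM. Over all 19 libraries Gc parted the genotype labels with these 2 libraries as the only exceptions. These levels are near the floor of the table, and which part of the gene the knockout removes is not given in the sources used here, so Gc alone does not check the labels. Groups below carry the genotype of their labels.

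Structural RNAs took a share of each library that differed with the groups. Rn7s1, Rn7s2 (the RNA of the signal recognition particle) and Rn7sk (a regulator of transcription elongation) together made up 24.8% ± 2.23 of TPM in WT saline (SD, n = 3), 37.0% ± 5.63 in labelled Gc-KO saline (SD, n = 3), 18.98% ± 7.50 in WT LLC (SD, n = 7) and 22.61% ± 11 in labelled Gc-KO LLC (SD, n = 6). The 2 libraries labelled Gc-KO LLC 5 and 6 had 36.7% and 35.5%, near the saline libraries of their genotype, while the libraries labelled Gc-KO LLC 1 to 4 had 12.97% to 22.3%. Rpph1, the RNA of ribonuclease P, ran with this share and averaged 774 ± 105 TPM in labelled Gc-KO saline (SD, n = 3) against 220 ± 16.9 TPM in WT saline (SD, n = 3). Because TPM have a fixed sum, a larger share of these RNAs leaves less for all other genes together, though not evenly. Nuclear protein-coding genes took 33.3% ± 5.82 in labelled Gc-KO saline and 34.7% ± 1.96 in WT saline (SD, n = 3 each). Mitochondrial-encoded genes took 14.9% ± 1.25 and 20.6% ± 0.924 (SD, n = 3 each). The median over all 12045 tested genes was 0.25 on the log2 scale for LLC in WT and 0.40 for LLC in labelled Gc-KO. It was -0.17 for labelled Gc-KO against WT in saline, -0.03 after LLC and 0.14 for the interaction. Median ratio scaling removes this shift. For the lists below, counts with scaling follow those as deposited, over all genes first and then over the list alone.

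**Figure D1:**
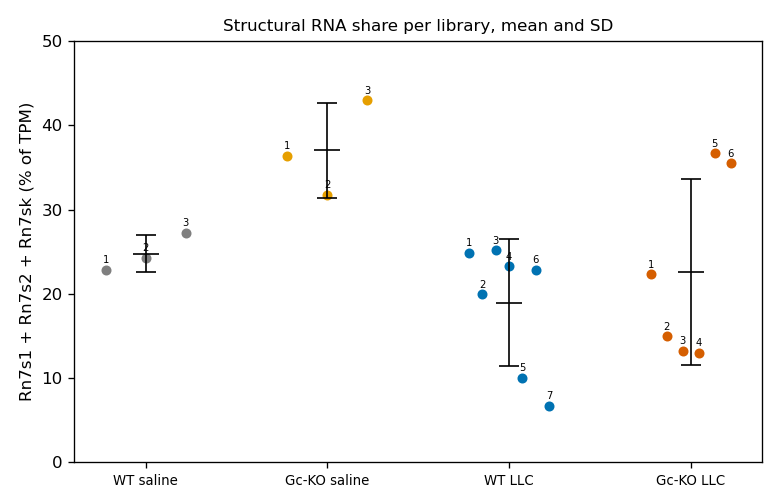
Share of TPM taken by Rn7s1, Rn7s2 and Rn7sk (vertical axis, % of TPM) in each of the 19 libraries, by group (horizontal axis). Points are libraries with their replicate numbers, bars the mean and SD; the saline libraries labelled Gc-KO lie at 31.7% to 43.0%, and of the libraries labelled Gc-KO LLC only 5 and 6, at 36.7% and 35.5%, reach that range.

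After LLC injection, WT muscle had genes of neutrophils and some of the muscle atrophy programme called higher. Some genes of fibrillar collagens and tendon were called lower. S100a8 and S100a9, which encode the calcium-binding calprotectin proteins of neutrophils, rose by 6.59 ± 0.36 and 6.33 ± 0.37 on the log2(TPM + 1) scale (SE; adjusted p = 3.6e-10 and 8.34e-10). S100a8 went from 1.43 ± 0.498 TPM (SD, n = 3) to 242 ± 73.6 TPM (SD, n = 7). Fbxo32 (atrogin-1, a ubiquitin ligase of wasting muscle, on chromosome 15 from 58175879 to 58214932) rose by 2.09 ± 0.37 (SE; adjusted p = 0.00248), from 60.03 ± 16 TPM (SD, n = 3) to 279 ± 152 TPM (SD, n = 7). Trim63 (MuRF1, a ubiquitin ligase of the sarcomere, on chromosome 4 from 134315120 to 134329629) rose by 2.23 ± 0.41 (SE; adjusted p = 0.00303), from 82.0 ± 7.06 TPM (SD, n = 3) to 424 ± 203 TPM (SD, n = 7). Both ligases stood above the highest WT saline library in 7 of 7 WT LLC libraries. Col1a1 and Col1a2, the chains of type I collagen, fell by 2.59 ± 0.31 and 2.23 ± 0.35 (SE; adjusted p = 7.46e-05 and 0.000892). Col1a1 went from 13.5 ± 1.98 TPM (SD, n = 3) to 1.42 ± 0.439 TPM (SD, n = 7) and was below every WT saline library in 7 of 7.

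Neutrophil, IL-6 family, glucocorticoid-responsive and atrophy genes had called members higher in WT. All 10 tested neutrophil genes were called higher, and 10 when adjusted over the list alone (with scaling 10 and 10). Among them were Retnlg, a granule protein gene of neutrophils (4.07 ± 0.35), and Ltf, which encodes lactoferrin and was listed at 0 in every WT saline library, so that no fold is given. For neutrophils camera gave adjusted p = 4.57e-15, and adjusted p = 0.0566 with an estimated correlation. Of 17 genes of the IL-6 family and the acute phase, 13 were higher and 14 when adjusted over the list alone (with scaling 10 and 14). Lcn2, an iron-scavenging acute phase protein, was at 2.15 ± 0.21, Osmr, the oncostatin M receptor, at 1.31 ± 0.21, and Socs3, a feedback inhibitor of cytokine signalling, at 1.02 ± 0.15. For the IL-6 family camera gave adjusted p = 8.46e-08, and adjusted p = 0.0566 with an estimated correlation. Of 20 glucocorticoid-responsive genes, 15 were higher and 15 when adjusted over the list alone (with scaling 11 and 15). The transcription factor genes Cebpd and Cebpb rose by 2.05 ± 0.34 and 1.71 ± 0.31, and Glul, the gene of glutamine synthetase, by 2.11 ± 0.39. For glucocorticoid response camera gave adjusted p = 2.07e-07, and adjusted p = 0.389 with an estimated correlation. Of 27 atrophy genes, 12 were higher and 14 when adjusted over the list alone (with scaling 10 and 10). Gadd45a, a growth arrest gene, rose by 1.68 ± 0.26 and Eda2r, the ectodysplasin A2 receptor, by 1.88 ± 0.36. For atrophy genes camera gave adjusted p = 4.49e-05, and adjusted p = 0.713 with an estimated correlation. Foxo1, a transcription factor gene of the atrophy programme, was 0.67 ± 0.39 higher (adjusted p = 0.243) and did not pass. Fbxo30, a further muscle ubiquitin ligase gene, was 0.44 ± 0.20 higher (adjusted p = 0.124) and did not pass either. Other inflammatory lists did not pass. Interferon response had 3 of 26 genes higher and 3 when adjusted over the list alone (with scaling 0 higher and 1 lower both ways; adjusted p = 0.965, and adjusted p = 0.996 with an estimated correlation). NF-kB and TNF response had 4 of 17 higher and 1 lower, and 4 and 1 when adjusted over the list alone (adjusted p = 0.76, and adjusted p = 0.962 with an estimated correlation). With scaling 1 was higher and 1 lower, and 2 and 1 over the list alone.

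Members of protein breakdown and protein synthesis lists were called higher in WT, fewer of them with scaling. Of 32 proteasome subunits, 13 were called higher and 27 when adjusted over the list alone (with scaling 5 and 5), including Psmd8 (1.11 ± 0.23) and Psmb1 (0.95 ± 0.20). The proteasome list had adjusted p = 8.81e-07, and adjusted p = 0.713 with an estimated correlation. Of 32 autophagy and lysosome genes, 13 were higher and 19 when adjusted over the list alone. With scaling 6 were higher, and 10 higher and 2 lower over the list alone. They include Ctsl, a lysosomal protease gene (1.09 ± 0.20), and Bnip3, a mitophagy receptor gene (1.43 ± 0.30). Map1lc3b, whose protein coats autophagosomes, rose by 0.90 ± 0.20 (adjusted p = 0.00892). The autophagy list had adjusted p = 0.00136, and adjusted p = 0.727 with an estimated correlation. Of 36 ribosomal protein genes, 26 were higher and 29 when adjusted over the list alone (with scaling 13 and 14). Many of these share reads with pseudogenes and are uncertain. The ribosomal list had adjusted p = 4.17e-11, and adjusted p = 0.251 with an estimated correlation. Of 9 erythroid genes, 7 were higher and 8 when adjusted over the list alone (with scaling 7 and 8). The haemoglobin genes Hbb-bt (3.20 ± 0.54) and Hbb-bs (2.76 ± 0.48) are near-identical and uncertain for the same reason. The erythroid list had adjusted p = 4.54e-05, and adjusted p = 0.389 with an estimated correlation. Of 13 macrophage and monocyte genes, 6 were higher and 7 when adjusted over the list alone (with scaling 5 and 6). Lyz2, the lysozyme gene, rose by 1.20 ± 0.24 and Ccr2, a chemokine receptor gene of monocytes, by 0.87 ± 0.18. The macrophage list had adjusted p = 0.00695, and adjusted p = 0.727 with an estimated correlation.

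Collagen and tendon lists had called members lower in WT after LLC. Of 25 collagen and matrix genes, 12 fell and 1 rose, and 15 and 1 when adjusted over the list alone (with scaling 17 and 1, and 21 and 1). Col3a1, the type III collagen gene, fell by 1.89 ± 0.37, while Lox, which cross-links collagen, rose by 1.23 ± 0.22. Collagens had adjusted p = 3.43e-23, and adjusted p = 0.103 with an estimated correlation. Of 8 tendon genes, 4 fell and 5 when adjusted over the list alone (with scaling 5 and 7). Tnmd (tenomodulin) fell by 1.71 ± 0.32 and Kera (keratocan) fell by 1.66 ± 0.30. Tendon had adjusted p = 2.41e-11, and adjusted p = 0.0566 with an estimated correlation. Of 13 transcripts of the mitochondrial genome, 2 fell and 4 when adjusted over the list alone (with scaling 6 and 7). The 2 were mt-Nd5 (-1.35 ± 0.35) and mt-Nd2 (-1.06 ± 0.33), subunits of respiratory complex I. Mitochondrial-encoded transcripts had adjusted p = 2.07e-07, and adjusted p = 0.389 with an estimated correlation. Fry did not call them as deposited (adjusted p = 0.253) and did with scaling (adjusted p = 0.0283). The exact permutation of list means called them neither way (adjusted p = 0.137, and 0.0841 with scaling). WT LLC 7 alone lay within the range of WT saline by list mean (12.21, WT saline 12.05 to 12.23), and with scaling no WT LLC library did. Slow and type IIA fibre genes passed with 0 of 14 called and 0 when adjusted over the list alone, as with scaling (adjusted p = 0.00154, and adjusted p = 0.727 with an estimated correlation). That call rested on WT LLC 1, whose mean over the list was 3.16 on the log2(TPM + 1) scale. The other 6 WT LLC libraries were at 6.46 to 7.48 and WT saline at 6.51 to 6.78. Without WT LLC 1 the list mean was 0.33 higher than in saline and camera gave adjusted p = 0.501, and without WT saline 2 adjusted p = 0.0593. Leaving out 1 library was chosen for the lists after the data were seen. Genes of fibro-adipogenic progenitors stood lower too, with 1 of 12 lower and 1 higher, and 2 and 1 when adjusted over the list alone (with scaling 3 and 1, and 6 and 1). Progenitors had adjusted p = 0.00136, and adjusted p = 0.713 with an estimated correlation. Sarcomere and Z-disc genes had 2 of 27 lower and 1 higher, and 1 and 1 when adjusted over the list alone (with scaling 3 and 1 both ways). Their median was 0.13, while relative to other genes the test put them lower (adjusted p = 0.0273, and adjusted p = 0.727 with an estimated correlation). Without WT saline 2, WT LLC 1 or WT LLC 7 that call was lost (adjusted p = 0.0808, 0.0947 and 0.0548), and the 13 other list calls were kept without any 1 library. Large falls outside these lists were those of Nrep, a gene of regenerating tissue (-2.08 ± 0.34), and Grb14, an adaptor that restrains insulin receptor signalling (-1.71 ± 0.35). Mrtfa, a coactivator of serum response factor, fell by 1.73 ± 0.41.

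In all, limma called 1616 of 12045 genes after LLC in WT, 1490 higher and 126 lower, and 315 changed by at least 1 on the log2 scale. With median ratio scaling it called 1320, of which 657 were higher and 663 lower. Called in the same direction both ways were 782 genes, the calprotectin genes, Fbxo32 (1.76), Trim63 (1.90) and Col1a1 (-2.84) among them. The small nucleolar RNAs Snora43 (the gene starting at 26637847 on chromosome 2, 1 of 2 genes of that name), Snora30, Snora52 and Snora21 were among the largest rises but were listed at 0 in every WT saline library, so no fold is given. Snora30 and Snora52 did not pass after scaling (adjusted p = 0.0516 and 0.0853). Scarna3a, a Cajal body RNA, was 3.53 ± 0.84 higher and passed both ways. The scaled list calls were lost for slow and type IIA fibres (adjusted p = 0.24) and for sarcomere and Z-disc genes (adjusted p = 0.0677), and the other 13 kept their direction. With scaling nuclear-encoded oxidative phosphorylation was called lower as well (adjusted p = 0.0183, and 0.0985 as deposited), with adjusted p = 0.881 with an estimated correlation as deposited. Fry with scaling did not call it (adjusted p = 0.314). With the structural RNA share as a covariate, chosen after the data were seen, all 15 list calls were kept. The count was 273 without WT saline 2, 638 without WT saline 3 and 918 without WT LLC 5. It was 1025 with no filter on low values, 737 without mitochondrial-encoded genes, 4594 with array weights and, in a setting chosen after the data were seen, 857 with nuclear protein-coding genes alone.

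**Figure D2:**
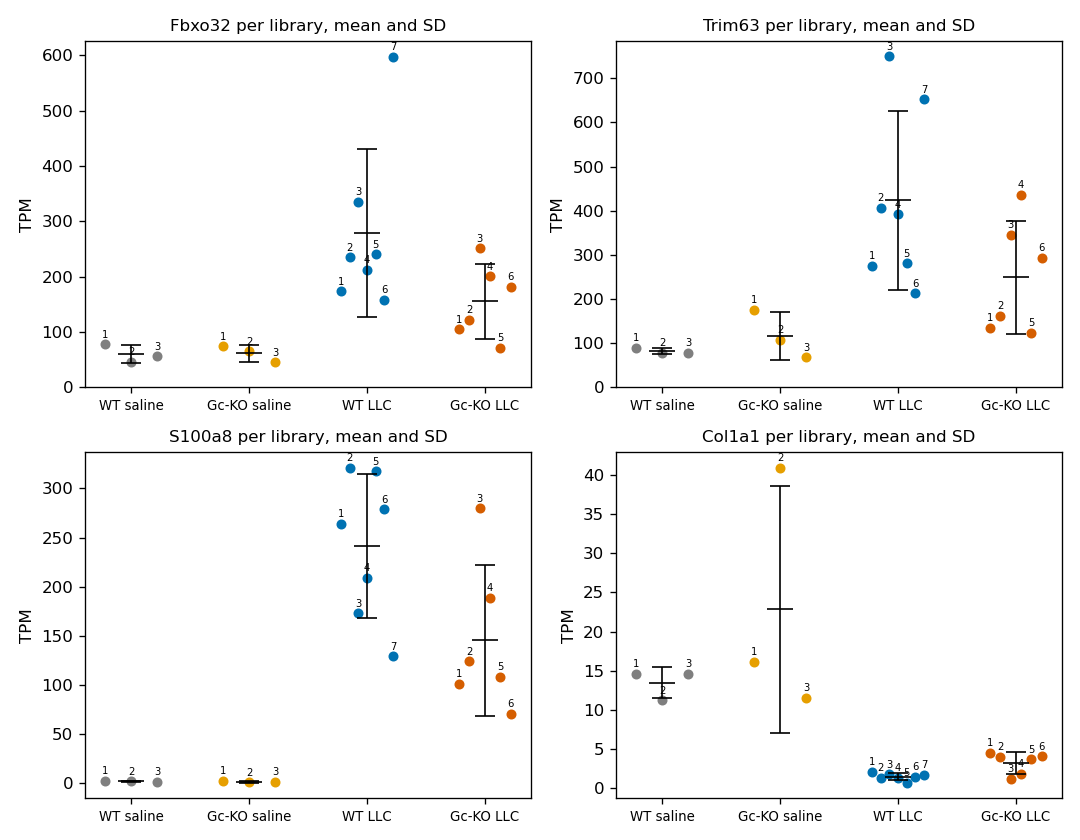
TPM (vertical axis) of Fbxo32, Trim63, S100a8 and Col1a1 in each library, by group (horizontal axis). Points are libraries with their replicate numbers and bars the mean and SD; Fbxo32, Trim63 and S100a8 of all 7 WT LLC libraries lie above the 3 WT saline libraries, with Fbxo32 at 598 TPM in WT LLC 7, and Col1a1 lies below them.

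Muscle labelled Gc-KO also had neutrophil genes called higher and some collagen and tendon genes called lower after LLC injection. S100a9 and S100a8 rose by 6.06 ± 0.38 and 6.04 ± 0.36 (SE; adjusted p = 3.03e-09 for both). S100a8 went from 1.15 ± 0.998 TPM (SD, n = 3) to 145 ± 76.7 TPM (SD, n = 6), and stood above every saline library of the genotype in 6 of 6. Wfdc17, a protease inhibitor gene of activated myeloid cells, rose by 2.59 ± 0.28 (adjusted p = 3.45e-05), and Retnlg by 3.15 ± 0.36 (adjusted p = 5.58e-05). Col1a1 fell by 2.40 ± 0.32 (adjusted p = 0.000322), from 22.8 ± 15.9 TPM (SD, n = 3) to 3.15 ± 1.36 TPM (SD, n = 6), lower in 6 of 6. The saline mean rests in part on labelled Gc-KO saline 2 at 40.96 TPM, with the others at 16.08 and 11.48 TPM, and without that library Col1a1 still passed. Col1a2 fell by 1.87 ± 0.36 (adjusted p = 0.0112), and the tendon genes Kera and Tnmd fell by 1.28 ± 0.31 and 1.23 ± 0.32 (adjusted p = 0.0241 and 0.0242). All of these passed after scaling too.

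Of the atrophy ligases, Fbxo32 passed in labelled Gc-KO as deposited but not after scaling, and Trim63 passed in neither. Fbxo32 rose by 1.24 ± 0.38 (SE; adjusted p = 0.0284), from 61.2 ± 14.7 TPM (SD, n = 3) to 155 ± 67.3 TPM (SD, n = 6), above every saline library of the genotype in 5 of 6. With scaling it was 0.71 higher (adjusted p = 0.289). Trim63 was 1.02 ± 0.42 higher (adjusted p = 0.0596), at 249 ± 129 TPM (SD, n = 6) against 117 ± 54.1 TPM (SD, n = 3), and did not pass. Fbxo30 (0.72 ± 0.20, adjusted p = 0.0259) and Map1lc3b (0.64 ± 0.20, adjusted p = 0.0306) rose as deposited. After scaling they stood at 0.26 (adjusted p = 0.374) and 0.12 (adjusted p = 0.601). Foxo1 was 1.01 ± 0.40 higher (adjusted p = 0.0566) and did not pass. Of the 27 atrophy genes, 16 were higher and 19 when adjusted over the list alone, and with scaling 0 and 0. The list had adjusted p = 0.0105, and adjusted p = 0.916 with an estimated correlation. Of 32 proteasome subunits 19 were higher and 22 when adjusted over the list alone, and of 20 glucocorticoid-responsive genes 7 and 9. With scaling 0 members of either list were called, and 0 over the list alone. Neither list passed against other genes as deposited (adjusted p = 0.132 and 0.375, and adjusted p = 0.916 with an estimated correlation for both). With scaling camera put glucocorticoid-responsive genes higher (adjusted p = 0.0348) and did not call proteasome subunits (adjusted p = 0.893).

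All 10 neutrophil genes were higher in labelled Gc-KO, and 10 when adjusted over the list alone (with scaling 5 and 9). Neutrophils had adjusted p = 6.93e-10, and adjusted p = 0.22 with an estimated correlation. Of 17 genes of the IL-6 family and acute phase, 12 were higher and 12 when adjusted over the list alone. With scaling 3 were higher, and 8 higher and 1 lower over the list alone. The 3 were Osmr at 1.64 ± 0.21, Lcn2 at 1.52 ± 0.21 and Socs3 at 0.89 ± 0.15. This list had adjusted p = 0.0155, and adjusted p = 0.651 with an estimated correlation. Of 9 erythroid genes, 8 were higher and 8 when adjusted over the list alone, and with scaling 0 and 8. Alas2, the first enzyme of haem synthesis in red cells, rose by 2.54 ± 0.54 as deposited, and the haemoglobin genes Hbb-bt (2.64 ± 0.55) and Hba-a2 (2.61 ± 0.56) are uncertain as above. After scaling Alas2, Hbb-bt and Hba-a2 did not pass (adjusted p = 0.0534, 0.0741 and 0.0892). Erythroid genes had adjusted p = 0.0014, and adjusted p = 0.778 with an estimated correlation. Of 25 collagen and matrix genes, 7 fell and 7 when adjusted over the list alone (with scaling 10 and 16), including Col12a1 (-0.88 ± 0.20) and Col5a1 (-0.75 ± 0.18). Collagens had adjusted p = 2.04e-28, and adjusted p = 0.109 with an estimated correlation. Fry did not call them as deposited (adjusted p = 0.146) and did with scaling (adjusted p = 0.00331). The exact permutation of list means called them neither way (adjusted p = 0.258, and 0.0979 with scaling). These group sizes allow no exact p below 0.0119, so a list passes after adjustment only if many lists reach that limit. List means overlapped, at 2.99 to 4.10 in saline and 2.62 to 3.65 after LLC, and with scaling they did not. Tendon was the 1 list that kept its call in that setting, with 4 of 8 genes lower and 4 when adjusted over the list alone (with scaling 4 and 8). It had adjusted p = 1.18e-19, and adjusted p = 0.0127 with an estimated correlation. By camera's preset correlation, lists of oxidative phosphorylation, glycolysis and fibre genes in labelled Gc-KO stood below other genes after LLC. Those of fatty acid oxidation and PPAR targets and of mitochondrial-encoded transcripts were not called. Nuclear-encoded oxidative phosphorylation had 0 of 47 genes called and 0 when adjusted over the list alone. Its median was 0.22 as deposited and -0.31 after scaling (adjusted p = 7.27e-06, and adjusted p = 0.793 with an estimated correlation). Slow and type IIA fibre genes stood lower too, with 0 of 14 called and 0 when adjusted over the list alone (adjusted p = 1.24e-07, and adjusted p = 0.651 with an estimated correlation). Adipocyte genes stood lower with 1 of 7 higher and 1 when adjusted over the list alone. Adipocytes had adjusted p = 0.000659, and adjusted p = 0.301 with an estimated correlation. Lower relative to other genes were also glycolysis (adjusted p = 0.0014), fast fibres (0.00204), fibro-adipogenic progenitors (0.0168), sarcomere and Z-disc (0.0212) and Schwann cells and nerve (0.039). Each of these had adjusted p = 0.793 with an estimated correlation. Between 0 and 4 of their members were called, all higher, and 0 to 3 when adjusted over the list alone. The medians of the first 4 were 0.10 to 0.25 as deposited, against the sign of their test. With scaling 10 of the 14 list calls were kept, and those of adipocytes, slow and type IIA fibres, progenitors, and Schwann cells and nerve were not. It then called 4 others, macrophages (adjusted p = 0.00322), endothelial cells (0.021) and glucocorticoid response (0.0348) higher and ribosomal proteins (0.0216) lower (adjusted p = 0.916 with an estimated correlation for each, as deposited). Over the 8 lists that stood lower with no called gene lower, 0 members were called with scaling, and 0 over the list alone, except 1 progenitor gene higher (over the list alone 1 higher and 5 lower). With the structural RNA share as a covariate, chosen after the data were seen, 10 of the 14 were kept. Those of progenitors (adjusted p = 0.102), glycolysis (0.148), fast fibres (0.42) and Schwann cells and nerve (0.644) were lost. Without any 1 library 8 of the 14 list calls were kept. Without labelled Gc-KO saline 2 those of atrophy genes (adjusted p = 0.0823), progenitors (0.438) and Schwann cells and nerve (0.412) were lost, and without saline 3 those of adipocytes (0.138) and Schwann cells and nerve (0.194). Without labelled Gc-KO LLC 5 the IL-6 family was lost (0.0649), without LLC 3 progenitors (0.0677), without saline 1 sarcomere and Z-disc (0.0723), and without LLC 1, 4 or 6 Schwann cells and nerve (0.104, 0.0524 and 0.094).

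In muscle labelled Gc-KO limma called 4230 genes after LLC, 4201 higher and 29 lower, of which 171 changed by at least 1 on the log2 scale. With median ratio scaling it called 86, of which 48 were higher and 38 lower, and 68 were called in the same direction both ways. The falls of Rpph1 (-2.03 ± 0.58) and of the liver genes Mup22 (-1.44 ± 0.56) and Apoc1 (-1.43 ± 0.53) did not pass after scaling (adjusted p = 0.108, 0.192 and 0.159), and Mup22 belongs to a family of near-identical genes. The count was 18 without labelled Gc-KO saline 3, 673 without saline 1, and 2725, 127, 126 and 2454 without labelled Gc-KO LLC 1, 2, 3 and 4 in turn. It was 59 with no filter, 94 with quantile normalization and 63 with only the groups compared. In settings chosen after the data were seen it was 204 with nuclear protein-coding genes alone, 52 with the structural RNA share as a covariate, 107 without WT LLC 4 and labelled Gc-KO LLC 3, and 12 with labelled Gc-KO LLC 5 and 6 as the only LLC libraries of the genotype.

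Of the genes called higher after LLC, 915 were shared between the genotypes where independent lists would share 520, and of those called lower 17 where independent lists would share 0.303. With scaling the shared genes were 43 where 2.62 would be shared and 29 where 2.09 would be. The group means of the 2 comparisons have separate saline controls and share no library. Both sets of calls come from the same fit, however, in which each gene has a variance taken over all groups. With each library labelled Gc-KO left out in turn, calls for LLC in WT were 1324 to 2002, against 1616 with all libraries. The calls are thus not independent, and the numbers for independent lists are a rough guide and not a test.

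Limma called 1 gene between the genotypes in saline muscle, while 1456 had an unadjusted p below 0.05. It was Gm31166, a transcribed processed pseudogene (chromosome 19, 5512528 to 5550368), which fell by 1.07 ± 0.17 in labelled Gc-KO (SE; adjusted p = 0.0291), from 8.52 ± 0.46 TPM in WT (SD, n = 3) to 3.55 ± 0.5 TPM (SD, n = 3), lower in 3 of 3. As a pseudogene it can share reads with its parent gene and is uncertain. The atrophy genes did not pass. Fbxo32 stood at 61.2 ± 14.7 TPM in labelled Gc-KO and 60.03 ± 16 TPM in WT (SD, n = 3 each; log2 difference 0.03 ± 0.44, adjusted p = 0.981). Trim63 stood at 117 ± 54.1 and 82.0 ± 7.06 TPM (SD, n = 3 each; 0.41 ± 0.48, adjusted p = 0.725). Map1lc3b (-0.19 ± 0.24), Foxo1 (-0.47 ± 0.47) and Fbxo30 (-0.40 ± 0.23) did not pass either (adjusted p = 0.745, 0.673 and 0.483). Higher without passing were the pseudogenes Gm8730 (4.82 ± 1.05, adjusted p = 0.16), Gm6278 (3.61 ± 0.83, adjusted p = 0.166) and Gm9625 (4.13 ± 0.99, adjusted p = 0.182). Lower without passing were the small nuclear RNA gene Gm22614 (-6.15 ± 1.06, adjusted p = 0.0636), Prune2 (-1.32 ± 0.24, adjusted p = 0.08) and Phactr4, a regulator of protein phosphatase 1 and actin (-1.16 ± 0.22, adjusted p = 0.08).

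**Figure D3:**
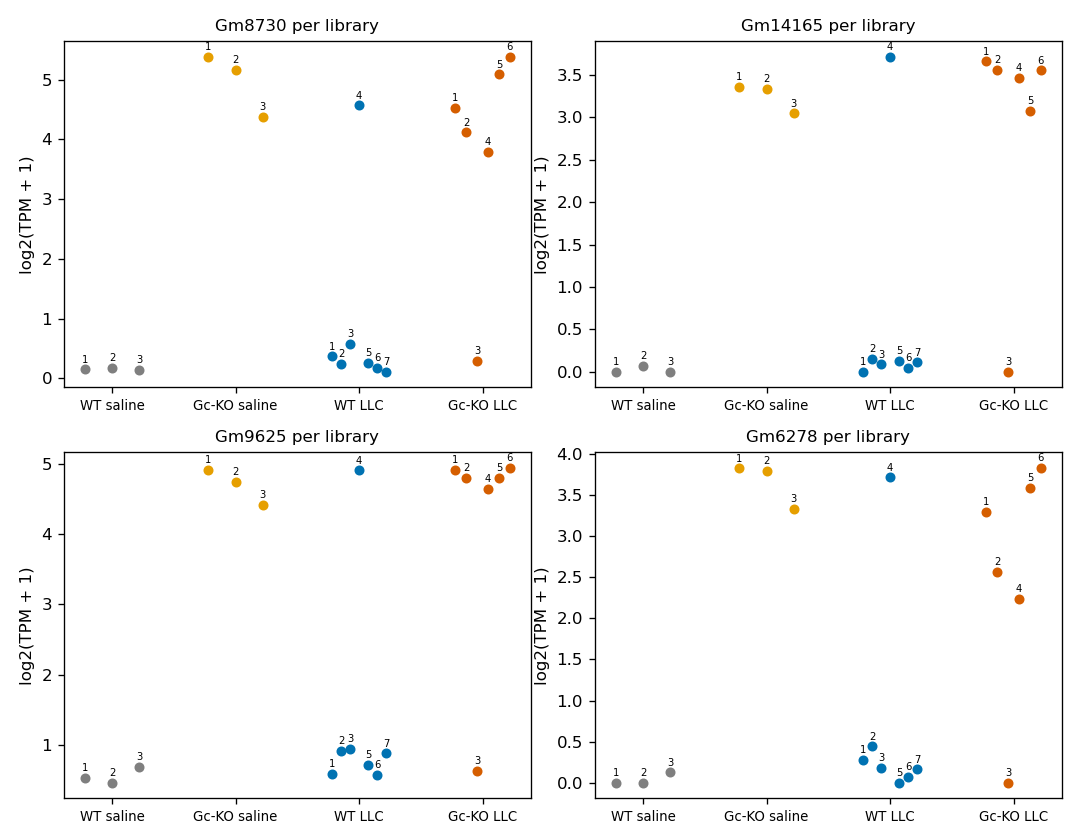
Level of Gm8730, Gm14165, Gm9625 and Gm6278 (vertical axis, log2(TPM + 1)) in each library, by group (horizontal axis). Points are libraries with their replicate numbers; WT LLC 4 lies among the libraries labelled Gc-KO and labelled Gc-KO LLC 3 among the WT libraries in all 4 panels.

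Camera's preset correlation called 10 gene lists between the genotypes in saline muscle, of which 0 were kept with an estimated correlation. The 13 transcripts of the mitochondrial genome were lower in labelled Gc-KO with a median of -0.99, 0 called over all genes and 8 when adjusted over the list alone (with scaling 0 and 7; adjusted p = 8.88e-05, and adjusted p = 0.759 with an estimated correlation). All mitochondrial-encoded genes together, not these 13 alone, took 14.9% ± 1.25 of TPM in labelled Gc-KO saline (SD, n = 3), where the structural RNA share was larger. In WT saline they took 20.6% ± 0.924 (SD, n = 3). Ribosomal protein genes stood higher, with 0 of 36 called and 1 when adjusted over the list alone (adjusted p = 2.8e-15, and adjusted p = 0.485 with an estimated correlation). With scaling 2 were called and 16 over the list alone, the median was 0.55 against 0.31 as deposited, and fry called the list (adjusted p = 0.0118). In all 10 of 37 lists passed, 9 higher and 1 lower. Camera with scaling passed 6, of which 5 were among the 10, and fry passed 0 as deposited and 2 with scaling. The 8 others passed at adjusted p of 0.000874 to 0.0177 with no member called, nor when adjusted over the list alone: Schwann cells and nerve, tendon, macrophages, glucocorticoid response, myogenesis, polyamine metabolism, immediate early genes and collagens (adjusted p = 0.759 to 0.971 with an estimated correlation). With scaling 2 myogenesis genes, 1 polyamine gene and 1 collagen gene passed over the list alone. The library labelled Gc-KO saline 2 stood highest of its group for collagens (list mean 4.10 against 3.33 and 2.99), tendon (3.60 against 2.86 and 2.76), macrophages (2.27 against 1.89 and 1.41) and Schwann cells and nerve (2.64 against 1.81 and 1.94). Without it the calls of collagens, macrophages and tendon were lost (adjusted p = 0.915, 0.117 and 0.1) and their list means stood below WT saline, while that of Schwann cells and nerve was kept. Kept without any 1 library were 3 of the 10 calls, mitochondrial-encoded transcripts, ribosomal proteins and Schwann cells and nerve. Of the 10 calls, 5 were kept without WT saline 1 and 5 without WT saline 3, 8 without WT saline 2 and 8 without labelled Gc-KO saline 3, and 9 without labelled Gc-KO saline 1. With the structural RNA share as a covariate, chosen after the data were seen, 6 of the 10 were kept. Those of macrophages (adjusted p = 0.0904), polyamine metabolism (0.128), collagens (0.182) and tendon (0.206) were lost.

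Of 12045 genes, 1 was called in saline and 1456 had an unadjusted p below 0.05. With scaling 32 were called, 14 higher and 18 lower. Other settings gave 0 without mitochondrial-encoded genes, 2 with a pseudocount of 5 or a mean TPM of at least 5, 20 with quantile normalization, 15 with only the groups compared and 264 with array weights. In settings chosen after the data were seen it was 8 with nuclear protein-coding genes alone, 7 without WT LLC 4 and labelled Gc-KO LLC 3, and 2 without labelled Gc-KO LLC 5 and 6 or 1 to 4. The count was 0 without any 1 of WT saline 1, WT saline 2, labelled Gc-KO saline 1, WT LLC 2 or labelled Gc-KO LLC 1, 4 or 6. It was 6 without WT saline 3, 5 without WT LLC 4, 4 without labelled Gc-KO LLC 3, 3 without WT LLC 6 or WT LLC 7 and 2 without labelled Gc-KO saline 3 or LLC 5. Without labelled Gc-KO saline 2 the 1 gene was Prune2. A genomic segment around a targeted gene can differ in a knockout line. In saline 0 of 40 tested genes within 10 Mb of Gc were called, and 1 of 12005 elsewhere (two-sided Fisher's exact p = 1; by limma 1456 of all tested genes had an unadjusted p below 0.05). With scaling Cox18, an assembly factor of cytochrome oxidase, was called within 10 Mb, and 31 elsewhere (two-sided Fisher's exact p = 0.101). With so few genes called, neither test can show or exclude a differing segment.

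After LLC injection no single gene passed between the genotypes. Camera's preset correlation put atrophy, neutrophil and adipocyte genes lower and collagen genes higher in muscle labelled Gc-KO, and 0 of these list calls were kept with an estimated correlation. Fbxo32 stood at 155 ± 67.3 TPM in labelled Gc-KO (SD, n = 6) and 279 ± 152 TPM in WT (SD, n = 7), a log2 difference of -0.82 ± 0.30 (SE; adjusted p = 1). Trim63 stood at 249 ± 129 and 424 ± 203 TPM, a difference of -0.80 ± 0.33 (adjusted p = 1). For both genes the libraries of the groups overlapped. Map1lc3b (-0.44 ± 0.16), Foxo1 (-0.13 ± 0.32) and Fbxo30 (-0.13 ± 0.16) did not pass either (adjusted p = 1 for each). Closest to passing were Slc15a2, a peptide transporter gene, at 1.21 ± 1.77 TPM in labelled Gc-KO (SD, n = 6) and 5.90 ± 2.78 TPM in WT (SD, n = 7; -1.79 ± 0.34, adjusted p = 0.36). Next were Gm14418 (-0.55 ± 0.12, adjusted p = 0.499), the lincRNA gene Gm30794 (1.00 ± 0.23, adjusted p = 0.499) and the pseudogenes Gm8783 (-1.81 ± 0.37, adjusted p = 0.36), Gm13194 (0.89 ± 0.18, adjusted p = 0.36) and Gm15801 (1.77 ± 0.39, adjusted p = 0.497). Pseudogenes share reads with other genes and are uncertain.

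By list, 12 of 37 passed after LLC with camera's preset correlation, 8 lower and 4 higher in labelled Gc-KO, and 0 with an estimated correlation. No member of any list was called over all genes, and the counts that follow are adjusted over the list alone. Glucocorticoid-responsive genes had 5 of 20 lower, with a median of -0.38 (adjusted p = 3.27e-08, and adjusted p = 0.35 with an estimated correlation). Adipocyte genes had 5 of 7 lower, with a median of -0.53 (adjusted p = 1.04e-08, and adjusted p = 0.0742 with an estimated correlation). Neutrophil genes had 3 of 10 lower (adjusted p = 5.42e-08, and adjusted p = 0.306 with an estimated correlation). Genes of the IL-6 family and acute phase had 1 of 17 lower (adjusted p = 0.000214, and adjusted p = 0.306 with an estimated correlation). Ribosomal protein genes had 1 of 36 lower (adjusted p = 0.000369, and adjusted p = 0.704 with an estimated correlation). Atrophy genes stood lower with 0 of 27 (adjusted p = 8.65e-06, and adjusted p = 0.704 with an estimated correlation). Proteasome subunits stood lower with 0 of 32 (adjusted p = 1.04e-08, and adjusted p = 0.668 with an estimated correlation). Autophagy and lysosome genes stood lower with 0 of 32 (adjusted p = 0.000903, and adjusted p = 0.737 with an estimated correlation). Collagens and matrix stood higher with 0 of 25 (adjusted p = 1.09e-12, and adjusted p = 0.35 with an estimated correlation). Tendon genes stood higher with 0 of 8 (adjusted p = 4.41e-06, and adjusted p = 0.306 with an estimated correlation). Fibro-adipogenic progenitors stood higher with 1 of 12 (adjusted p = 1.55e-06, and adjusted p = 0.35 with an estimated correlation). Macrophages stood higher with 0 of 13 (adjusted p = 0.00357, and adjusted p = 0.724 with an estimated correlation), a call lost without WT LLC 4, WT LLC 7, labelled Gc-KO LLC 2 or LLC 5 (adjusted p = 0.0543 to 0.137). The other 11 were kept without any 1 library. With scaling 0 members were called over all genes. Over the list alone 2 glucocorticoid-responsive, 2 autophagy, 3 adipocyte and 1 IL-6 family genes were then lower and 3 collagen and 1 progenitor genes higher.

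For these genotypes after LLC, limma called 0 of 12045 genes, 416 had an unadjusted p below 0.05 and the smallest adjusted p was 0.36. With scaling it called 0 with 691 below 0.05. Fry called 0 lists with and without scaling. An exact permutation test of list means per library left 1, adipocytes, at a difference of -0.52 (exact p = 0.00117, adjusted p = 0.0431). It had an adjusted p of 0.172 with scaling and of 0.12 without WT LLC 4 and labelled Gc-KO LLC 3. The limma count was 3 without WT LLC 4 and 3 without labelled Gc-KO LLC 3 (Gm14165, Gm8730 and Gm9625 each time), and 1, Slc15a2, without labelled Gc-KO LLC 6. Without both WT LLC 4 and labelled Gc-KO LLC 3 it was 7. With all libraries 0 of 40 tested genes within 10 Mb of Gc were called, which follows from 0 called in all.

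No gene's response to LLC cells was shown to differ between the genotypes. The rise of Trim63 was smaller in labelled Gc-KO by 1.21 ± 0.58 on the log2 scale (SE; adjusted p = 0.689) and that of Fbxo32 by 0.85 ± 0.53 (adjusted p = 0.725). The differences for Map1lc3b (-0.25 ± 0.29), Foxo1 (0.34 ± 0.57) and Fbxo30 (0.27 ± 0.28) did not pass either (adjusted p = 0.853, 0.901 and 0.835). The closest were Bhlhe41, a clock repressor gene, at 1.49 ± 0.28, Hipk2, a kinase gene, at 1.49 ± 0.29, and the antisense gene Foxo6os at 1.18 ± 0.24 (adjusted p = 0.286 for each). Smaller in labelled Gc-KO without passing were the ribosomal protein gene Rpl9-ps6, annotated as protein-coding, (-0.93 ± 0.23, adjusted p = 0.42), Cfd, an adipocyte complement factor gene (-1.45 ± 0.40, adjusted p = 0.499), and the small nucleolar RNA gene Gm26175 (adjusted p = 0.538), listed at 0 in every WT saline library, so no fold is given. Bhlhe41 stood at 11.7 ± 1.58 TPM in WT saline and 4.71 ± 0.679 TPM in labelled Gc-KO saline (SD, n = 3 each), and at 5.61 ± 1.71 TPM (SD, n = 7) and 7.26 ± 1.49 TPM (SD, n = 6) after LLC.

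Limma called 0 of 12045 genes for the interaction, with 869 at an unadjusted p below 0.05 and a smallest adjusted p of 0.286, and with scaling 0 with 1495 below 0.05. Camera passed 12 of 37 lists, 11 lower and 1 higher, of which 0 passed with an estimated correlation. Fry passed 0 lists as deposited and 3 with scaling. With the structural RNA share as a covariate, chosen after the data were seen, 11 of the 12 list calls were kept, and that of Schwann cells and nerve was lost (adjusted p = 0.0817). The limma count was 45 with array weights and, in settings chosen after the data were seen, 5 with nuclear protein-coding genes alone (Bhlhe41, Ctdnep1, Hipk2, Kmt5a and Rpl9-ps6) and 4 without labelled Gc-KO LLC 5 and 6 (Bhlhe41, Hipk2, Kmt5a and Pon3). It was 2 without WT LLC 6 (Gm24830 and Gm26232), 1 without labelled Gc-KO saline 3 (Gm22614) and 1 without labelled Gc-KO LLC 5 (Hipk2).

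Over the 4912 genes called after LLC in either genotype, the effect in labelled Gc-KO had a slope of 0.771 on the effect in WT (jackknife SE over libraries 0.45). The slope was 0.580 over genes called in WT, 1.07 over genes called in labelled Gc-KO and 0.406 with scaling. The error was computed for the slope of 0.771 alone, which with it was not distinguishable from 1. Since the slope moved with the genes selected, 1 is no sure mark of equal responses. Whether the genotype difference after LLC ran against the LLC effect of WT was asked with the WT LLC libraries split between the 2 effects, since a shared group alone makes them run opposite. Over 1776 genes the correlation across genes, which are not independent replicates, was -0.443 with a covariance of -0.0711, against -0.041 ± 0.23 and -0.0017 ± 0.011 (SD) in 100 simulations of unchanged groups. With odd and even libraries exchanged it was -0.649 over 157 genes, and over all 12045 tested genes it was -0.135. A further simulation, chosen after the data were seen, gave the same LLC effect to both genotypes and returned 0.046 ± 0.22 with a covariance of 0.0067 ± 0.03, and 0 of its 100 runs were as negative as the data.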

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

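The 9 tests that weigh the patterns below were chosen only after the results were seen; the 5 counts over other splits of the libraries were planned.

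Single libraries stood far from their group for 9 of 104 gene and group combinations examined, where chance alone gives about 5.2. Fbxo32 was at 597.71 TPM in WT LLC 7, with the other WT LLC libraries at 158.16 to 335.62 TPM. Mrtfa was at 10.78 TPM in WT LLC 1 (others 0.82 to 3.26 TPM) and Slc15a2 at 4.74 TPM in labelled Gc-KO LLC 6 (others 0.07 to 0.97 TPM). The antisense gene Foxo6os was at 0.95 TPM in WT LLC 6 (others 0.29 to 0.46 TPM). The other 5 concern the libraries WT LLC 4 and labelled Gc-KO LLC 3: Gm8730 at 22.77 TPM, Gm6278 at 12.19 TPM, Gm9625 at 29.08 TPM and Gc at 0.47 TPM in WT LLC 4, and Gm9625 at 0.55 TPM in labelled Gc-KO LLC 3, where the others of that group were at 23.97 to 29.75 TPM.

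Processed pseudogenes on 4 chromosomes part the libraries by genotype label with the same 2 exceptions, WT LLC 4 and labelled Gc-KO LLC 3. Gm14165, Gm8730, Gm9625 and Gm6278 were the 4 of 10 genes with a wide gap between the saline genotypes that followed the labels in the other 11 LLC libraries. Gm14165 stood at 7.26 to 11.67 TPM in the other libraries labelled Gc-KO and 0 to 0.11 TPM in the other WT libraries, at 12.12 TPM in WT LLC 4 and 0 TPM in labelled Gc-KO LLC 3. Argued against is RNA mixed between libraries, since labelled Gc-KO LLC 3 was above the other WT libraries for 0 of the 4 markers. Exchanged labels of these 2 libraries remain a candidate explanation, with both on the other side for 4 of 4 markers. The 4 may not be independent, since pseudogenes can share reads with each other and with a parent gene. Rplp0 ran the opposite way with the same 2 exceptions. It stood at 79.84 to 137.43 TPM in the other libraries labelled Gc-KO and 142 to 288.08 TPM in the other WT libraries. WT LLC 4 was at 109.49 TPM and labelled Gc-KO LLC 3 at 151.7 TPM. Whether the markers share reads with Rplp0 was not tested. Variants that segregate independently of each other stay open: the 4 were chosen for following the labels elsewhere, and all 10 genes gave 6 partitions of the LLC libraries. The Gc transcript, not chosen by this rule but near the floor, had the same 2 exceptions. No library was relabelled, and no biological explanation was tested.

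After LLC in muscle labelled Gc-KO, 4201 of the 4230 called genes were higher. A few structural RNAs taking a large share of TPM are argued against as the whole of the one-sidedness. Over nuclear protein-coding genes alone, rescaled to their own sum, the median was still 0.206 (jackknife SE over libraries 0.0542; 0.40 over all genes as deposited) and 91.18% of calls were higher. With the structural RNA share as a covariate the median over all tested genes was 0.26, and 52 genes were called, all among the 4230. Of these 98.08% were higher, which does not speak to the many genes that lost their call. The near balance with median ratio scaling (86 called, 48 higher) follows from its centring. For the number of calls these RNAs stay open: it was 204 with nuclear protein-coding genes alone, but also 59 with no filter and 63 with only the groups compared, which leave these RNAs in. Library batches of high structural RNA content are a candidate explanation: set against the saline libraries, labelled Gc-KO LLC 5 and 6 gave 12 called genes, of the other 14 pairs 0 gave fewer, 3 gave as many, and labelled Gc-KO LLC 2 and 3 gave 5895. Against it, labelled Gc-KO LLC 1 and 4, with shares of 22.3% and 12.97%, gave 16. The labels give no batch, so whether the share itself follows from handling, genotype or the tumour was not tested. The rises of S100a8 and S100a9 do not rest on this. Both were called with and without scaling, and with labelled Gc-KO LLC 5 and 6 as the only LLC libraries of the genotype. Fewer of the other neutrophil genes were called with scaling, as given above.

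Between the genotypes after LLC, camera called 12 gene lists where limma called 0 genes and 416 had an unadjusted p under 0.05. A trend with the structural RNA share is argued against as the whole of it. With the share as a covariate 11 lists, all but macrophages, kept their call and direction. Without WT LLC 4 and labelled Gc-KO LLC 3, 12 lists kept theirs, so the calls do not rest on these 2 libraries. That setting cannot weigh exchanged labels, since an exchange would weaken a genotype difference rather than make it. Genes of a list varying together between mice remain a candidate explanation, since 0 lists kept their call with an estimated correlation. A genotype effect stays open and untested beyond this; adipocytes alone passed the permutation of list means (adjusted p = 0.0431), and did not without WT LLC 4 and labelled Gc-KO LLC 3 (adjusted p = 0.12) or with scaling (adjusted p = 0.172).

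The LLC effect differed between genotypes for 12 lists by camera on the interaction, where limma called 0 genes with 869 at an unadjusted p under 0.05, 0 lists passed with an estimated correlation, and by fry 0 as deposited and 3 with scaling. Relative to other genes, the LLC effect in labelled Gc-KO was lower for ribosomal proteins (adjusted p = 3.49e-19, and adjusted p = 0.243 with an estimated correlation), glucocorticoid response (4.01e-07, and 0.581), adipocytes (5.77e-05, and 0.278), neutrophils (7.82e-05, and 0.581), proteasome subunits (0.000347, and 0.91) and the IL-6 family and acute phase (0.000378, and 0.325). It was also lower for autophagy and lysosome (0.00829, and 0.91), myogenesis and satellite cells (0.0136, and 0.598), immediate early genes (0.0136, and 0.581), Schwann cells and nerve (0.017, and 0.791) and atrophy genes (0.0451, and 0.91). It was higher for mitochondrial-encoded transcripts, with a median of 1.00 (2.41e-05, and 0.598). The median over all tested genes was 0.14. Medians nearest 0 were those of proteasome subunits (-0.031), autophagy and lysosome (-0.084), atrophy genes (-0.10) and the IL-6 family (-0.13). The other lower lists had medians of -0.18 to -0.59. For ribosomal and mitochondrial-encoded lists the saline groups also differed, as given above, and that difference enters the interaction. No member was called over all genes, and when adjusted over the list alone 7 mitochondrial-encoded transcripts were higher, 1 adipocyte gene was lower, and no member of the other 10 lists passed. With scaling 17 ribosomal, 4 autophagy, 2 myogenesis and 2 adipocyte genes were lower over the list alone and 5 mitochondrial-encoded transcripts higher. With scaling 8 of the 12 kept their call, and those of atrophy genes (adjusted p = 0.165), the IL-6 family and acute phase (0.0553), immediate early genes (0.165) and Schwann cells and nerve (0.165) did not. Without any 1 library 7 of the 12 kept their call. That of atrophy genes was lost without any 1 of 11 libraries, and those of Schwann cells and nerve, myogenesis, immediate early genes and autophagy without any 1 of 5, 2, 2 and 1.

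Outside the tested genes, Alb, the serum albumin gene of liver, was at 76.34 TPM in labelled Gc-KO saline 2. It was at 1.81 and 0.82 TPM in labelled Gc-KO saline 1 and 3, and at 0 to 0.35 TPM in the other groups.

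Other splits of the same libraries show how often another grouping gave as many called genes. For LLC in WT 100 of the 120 possible splits were run. Of these 1, the real one, gave as many genes (1616, highest other 2), so chance is an unlikely account. For LLC in labelled Gc-KO 3 of 84 splits did (4230, highest other 4406). That share is under 0.05, but another split called more genes than the real split, so chance is not excluded. The highest exchanges the 3 saline libraries with labelled Gc-KO LLC 2, 3 and 4, those with the lowest structural RNA shares (14.9%, 13.2% and 12.97%), which points to a structure of the samples. For the genotypes in saline the 10 splits are too few (1 gene, highest other 1, reached by 2 splits). The splits decide nothing for the genotypes after LLC (0 genes, highest other 7, 100 of 100 splits as large) or for the interaction (0 genes, highest other 9, 100 of 100), since any split gives at least 0.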

How the results depend on the processing

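All settings named here with WT LLC 4 and Gc-KO LLC 3, Gc-KO LLC 5 and 6 or Gc-KO LLC 1 to 4 left out, with the structural RNA share as covariate, with nuclear protein-coding genes alone, with a permutation of list means or, for the called lists, with each library left out were chosen only after the data were seen; Gc-KO is as labelled. TPM hide the sequencing depth, no alternative restores it, array weights stopped before their convergence tolerance, and the interaction needs all 4 groups, so only the groups compared gives it no value. Where a count moved, the cause was not tested except for fewer genes or libraries.

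Called genes for LLC in WT (1616) were 1025 with no filter, 737 with mitochondrial-encoded genes left out, 4594 with array weights and 857 with nuclear protein-coding genes alone, and 273 to 2002 with each library left out in turn. For LLC in Gc-KO (4230) they were 59 with no filter, 86 with median ratio scaling, 94 with quantile normalization, 63 with only the groups compared, 107 with WT LLC 4 and Gc-KO LLC 3 left out, 39 with both changes, 12 with Gc-KO LLC 1 to 4 left out, 52 with the structural RNA share as covariate, 204 with nuclear protein-coding genes alone, and 18 to 5566 with each library left out. For the genotypes in saline (1) they were 2 with a pseudocount of 5, a mean TPM of at least 5, Gc-KO LLC 5 and 6 left out or Gc-KO LLC 1 to 4 left out, 0 with mitochondrial-encoded genes left out, 32 with median ratio scaling, 20 with quantile normalization, 15 with only the groups compared, 264 with array weights, 7 with WT LLC 4 and Gc-KO LLC 3 left out, 10 with these left out and scaling, 8 with nuclear protein-coding genes alone, and 0 to 6 with each library left out. For the genotypes after LLC (0 by limma, 416 at an unadjusted p under 0.05) they were 7 with WT LLC 4 and Gc-KO LLC 3 left out, 5 with scaling as well, 1 (Slc15a2) with Gc-KO LLC 5 and 6 left out, 1 (7530428D23Rik) with Gc-KO LLC 1 to 4 left out, and 0 to 3 with each library left out. Of the 7, Gm14165, Gm8730, Gm9625 and Gm6278 are markers picked for those libraries and no independent evidence. Rplp0, Rplp0-ps1 and Gm14418 are not among the markers. Rplp0 and Rplp0-ps1 part the libraries with the same 2 exceptions and may share reads with the markers, which was not tested. For the interaction (0 by limma, 869 at an unadjusted p under 0.05) they were 45 with array weights, 4 with Gc-KO LLC 5 and 6 left out, 5 with nuclear protein-coding genes alone, and 0 to 2 with each library left out.

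Camera with an estimated correlation called 0 lists for LLC in WT, 1 for LLC in Gc-KO, and 0 for each of the genotypes in saline, the genotypes after LLC and the interaction, and fry called 0 in the last 3. In saline 6 lists were called with median ratio scaling and 0 by permutation of list means, and after LLC 1 by that permutation. With WT LLC 4 and Gc-KO LLC 3 left out it called 0 for LLC in Gc-KO and 0 for either genotype comparison. The Gc difference after LLC was 0.329 to 0.463 on the log2 scale with each library left out, and in saline 0.312 to 1.63. The slope of the LLC effects was 0.492 without Gc-KO saline 3 to 0.902 without WT saline 2, and the reversal correlation over all tested genes was -0.135.

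Single results that changed sign had not passed in either direction under the alternative. Fbxo32, Gc-KO against WT in saline, was -0.0696 with mitochondrial-encoded genes left out, and -0.136, -0.00215, -0.118 and -0.0251 without WT saline 2, WT saline 3, Gc-KO saline 1 and Gc-KO saline 2, and at most 0.233 without Gc-KO saline 3. Map1lc3b, Gc-KO against WT in saline, was 0.0476 with scaling, 0.0134 without Gc-KO saline 3 (lowest -0.312 without Gc-KO saline 2), 0.0298 with the structural RNA share as covariate and 0.0458 with scaling and WT LLC 4 and Gc-KO LLC 3 left out. Foxo1, Gc-KO against WT in LLC, was 0.0250 without Gc-KO LLC 1, 0.0595 without Gc-KO LLC 5 (lowest -0.376 without Gc-KO LLC 3), 0.236 with Gc-KO LLC 5 and 6 left out and 0.0295 with the covariate, and Fbxo30, Gc-KO against WT in LLC, was 0.0728 with Gc-KO LLC 5 and 6 left out. With Gc-KO LLC 1 to 4 left out, Foxo1, genotype by LLC interaction, was -0.395 and Fbxo30, genotype by LLC interaction, was -0.133. Neb, LLC against saline in Gc-KO, was -0.0181 with scaling and WT LLC 4 and Gc-KO LLC 3 left out, and Grsf1, LLC against saline in Gc-KO, was -0.0172 with scaling and -0.0427 with those libraries left out as well. With scaling, of the single genes and lists 175 kept their direction and side of the threshold, 119 lost their call and 3 gained one.

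Replicate numbers used as a block gave 801 called genes for LLC in WT and 2 for the genotypes in saline (Gm22614 and Phactr4). The numbers do not pair the libraries: the residuals of 21 pairs with the same number had a mean correlation across genes of 0.00174, those of 108 other pairs -0.000382, and 5 of 19 libraries were closest to one of their own number.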

Other observations

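The permutation of list means per library and the simulation with the same LLC effect in both genotypes were chosen only after the results were seen.

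Further genes rose after LLC in WT muscle in lists that did not pass against other genes. Mstn, the gene of myostatin, which restrains muscle growth, was 1.20 ± 0.25 higher (SE; adjusted p = 0.00588), Xbp1, a transcription factor gene of the unfolded protein response, 1.00 ± 0.19 (adjusted p = 0.00322), and Il1b, the interleukin 1 beta gene, 1.42 ± 0.22 (adjusted p = 0.000854). Genes of the neuromuscular junction and of denervated muscle had 6 of 18 members higher and 6 when adjusted over the list alone (with scaling 3 higher and 2 lower, and 6 and 3), including Musk (1.05 ± 0.25) and Myog (0.82 ± 0.18; adjusted p = 0.992, and adjusted p = 0.996 with an estimated correlation). Endothelial genes had 6 of 14 members higher and 6 when adjusted over the list alone (adjusted p = 0.271, and adjusted p = 0.888 with an estimated correlation), and in labelled Gc-KO 7 and 9 (adjusted p = 0.0918, and adjusted p = 0.916 with an estimated correlation), with Pecam1 0.91 ± 0.23 and 1.01 ± 0.23 higher. With scaling 1 endothelial gene was higher and 2 lower in WT, and 0 were called in labelled Gc-KO, with 2 and 2 over the list alone in WT and 3 higher in labelled Gc-KO. Vitamin D pathway genes had 1 of 8 members higher after LLC in WT and 3 in labelled Gc-KO, and 1 and 3 when adjusted over the list alone (adjusted p = 0.965 and 0.809, and adjusted p = 0.996 and 0.916 with an estimated correlation), and with scaling 0 in either.

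The library labelled Gc-KO saline 2 held the highest level of 14 of 14 liver plasma protein genes, Gc among them. Apoa2 stood at 21.96 TPM there and at most 0.32 TPM elsewhere, Ahsg at 12.06 and 0.35 TPM, Trf, which muscle also expresses, at 42.84 and 28.71 TPM, and Gc at 6.55 and 0.59 TPM. The falls of Mup22 and Apoc1 after LLC in labelled Gc-KO start from a saline group that includes this library.

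Permutation of list means per library kept 19 lists for LLC in WT, 18 for LLC in labelled Gc-KO, 0 for the genotypes in saline, where the exact p cannot go below 0.1, and 1 for the genotypes after LLC. With scaling it kept 8 for LLC in WT and 0 for each of the other 3. Without WT LLC 4 and labelled Gc-KO LLC 3 it kept 19 for LLC in WT and 0 for the other 3, with a smallest adjusted p of 0.0601 for LLC in labelled Gc-KO, where the group sizes left allow no exact p below 0.0179, and of 0.12 for the genotypes after LLC. With all WT LLC libraries in both effects, the correlation across genes of the genotype difference with the LLC effect was -0.722, against -0.4 ± 0.18 (SD) in simulated unchanged groups.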
